A study of Mus musculus with 4 samples.

How the data were processed

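RNA from mouse bone marrow mesenchymal stem cells was measured on 4 Affymetrix arrays, 1 for each of Snail1-WT and Snail1-KO cells, untreated or treated with TGF-b1 for 2 h. Per the labels' protocols, total RNA was biotin-labelled with the WT PLUS kit. The authors deposited log2 values that were made with RMA in R 3.1.1, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises probes into probe sets, so a shift of most genes in the same direction would be removed. The deposited log2 values ran from 0.737 to 13.3 and their quartiles were nearly equal on the 4 arrays. The genome build and the annotation used by the authors are not given in the sources used here. Arrays have no sequencing depth, and their number limits the precision.

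Groups were taken from the sample titles. Gene names came from the platform annotation. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not named here. Of the former, 23328 matched a RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 of these had another symbol there. That table also served to order genes along chromosomes, and no coordinates from it are printed. Each of 22180 genes was represented by its probe set with the highest mean, and 1082 genes had more than 1. The 60% of genes with the highest mean over the 4 arrays were kept, which left 13308 genes with means of at least 4.51.

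With 1 array per group, no group can be tested against another group by itself. Differences of log2 values between arrays are given per gene, and genes at least 2-fold apart were counted. The genotype difference was required in both pairs of arrays, untreated and treated, which share no array, and the overlap was set beside the product of both counts divided by the number of genes. The noise SD of a difference between 2 arrays was taken from the difference of the responses divided by the square root of 2, as the SD within a quintile by level and, for a named gene, from the median absolute deviation among the 500 genes nearest in level. A secondary fit with limma 3.58.1 in R 4.3.3 (lmFit on genotype plus treatment, eBayes with a trend, Benjamini-Hochberg adjustment, threshold 0.05) used all 4 arrays. In data simulated on 13308 genes with 200 changed, it recovered 83.5% of 1.5-fold and 100% of 2-fold genotype changes, and 79.5% and 99.5% of such treatment changes. The simulated noise was normal, depended on level alone and held no genotype-specific response, as the fit assumes. These rates are therefore best cases and do not carry over to the real arrays. The 25 gene lists were described by the median difference of all measured members, whatever their level, and its percentile among 10000 random lists matched on mean level, with percentiles under 2.5 or over 97.5 taken as standing apart. Over 200 lists of 15 random genes in the Snail1-WT response, 3 were called higher and 4 lower, and with their medians set to 0.3 all 200 were called higher. Both outcomes follow from the construction, so they check only that the procedure ran properly. They do not show how often real lists, whose genes may vary together, would be called without a true shift. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

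Named genes followed a rule fixed before the data were examined: Snai1, the 12 largest increases and 12 largest decreases of each response to TGF-b1, the 12 genes in each direction with the largest genotype difference (the smaller of both pairs), the 8 largest differences of the responses in each direction, all at least 2-fold, and up to 4 members per list. Predicted gene models, clone-named transcripts, small RNA, olfactory and vomeronasal receptor, ribosomal pseudogene, immunoglobulin and T cell receptor segment symbols were left out of naming, not of counts. A few list members and marker genes were added after their values were seen. These are Acta2, Col1a1, Cdh1, Ptprc, Pecam1, Cd68, Cd14, Adgre1, Itgam, Csf1r, Lmod1, Smtn, Mki67, Mmp10 and Mmp13, and Olfr370, an exception to the symbols left out. Alternatives fixed at the same time were a 1.5-fold threshold, no filter, a filter at 40%, median centring, cyclic loess, the mean of all probe sets per gene and other eBayes settings.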

Results

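Gene expression was measured in mouse bone marrow mesenchymal stem cells, the adherent stromal cells that can form bone, cartilage and fat. Cells carried either functional Snail1 (Snail1-WT) or no functional Snail1 (Snail1-KO). Snail1, the product of the gene Snai1, is a zinc finger repressor best known for silencing the epithelial cadherin gene Cdh1. Cells of each genotype were left untreated or given TGF-b1, a cytokine that signals through SMAD proteins, for 2 h. Each of the 4 groups had 1 array, so no difference between 2 arrays has a replicate check, and whether the cultures came from separate animals is not given in the sources used here. Values are RMA log2 values, and a difference of 1 is 2-fold. Array medians over 41345 probe sets lay between 4.58 and 4.63. As a yardstick of error, the SD expected of a difference between 2 arrays was estimated from the disagreement of the 2 responses to TGF-b1. It was 0.24 for the lowest quintile of the 13308 genes analysed by level and 0.10 for the highest. True differences between the responses are included in it. Whatever both arrays of a genotype share, or both treated arrays share, cancels out of it. Set beside a genotype difference, it therefore leaves out any spread between cultures that both pairs share.

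The targeted gene was examined first. Snai1 measured 6.69 in untreated Snail1-WT cells and 7.63 after TGF-b1, against 5.09 and 5.34 in Snail1-KO cells. Snail1-KO minus Snail1-WT was thus -1.60 without and -2.29 with TGF-b1. The noise SD at its level was 0.18. The direction was that of the labels in both pairs. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal in Snail1-KO cells is not a measure of leftover protein. The response of Snai1 itself to TGF-b1 was 0.94 in Snail1-WT cells and 0.25 in Snail1-KO cells.

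**Figure D1:**
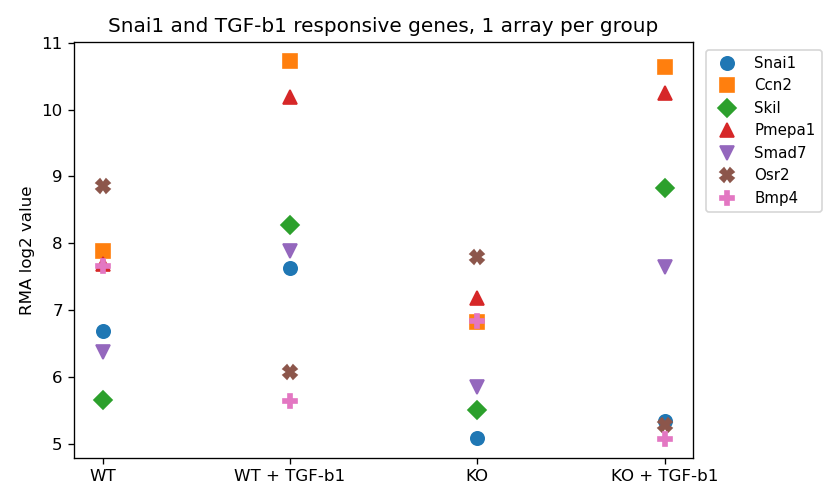
RMA log2 values (vertical axis) of Snai1, 4 genes higher after TGF-b1 (Ccn2, Skil, Pmepa1, Smad7) and 2 lower after it (Osr2, Bmp4) on each of the 4 arrays (horizontal axis), with 1 point per array and no error bars because each group has 1 array. Snai1 lies at 5.09 and 5.34 on the Snail1-KO arrays and at 6.69 and 7.63 on the Snail1-WT arrays.

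In Snail1-WT cells after 2 h of TGF-b1, the matricellular growth factor gene Ccn2 was higher by 2.84, the SMAD co-repressor gene Skil by 2.62 and Pmepa1, a membrane protein gene that dampens SMAD signalling, by 2.51. The hyaluronan synthase gene Has2 was higher by 2.61, the zinc finger regulator Egr2 by 2.64 and the EGF receptor ligand Hbegf by 2.14. Gfpt2, which feeds the hexosamine pathway, was higher by 2.14, the vasopressin receptor gene Avpr1a by 1.97 and Tnfrsf11b, encoding the osteoclast inhibitor osteoprotegerin, by 1.82. Rasl11b, Zfp469 and Rflnb completed the 12 largest increases at 1.82, 1.81 and 1.81. Rasl11b measured 4.16 in untreated Snail1-WT cells, below 4.51, the lowest mean kept, so the size of its increase is uncertain. Among the largest decreases were the limb regulator Osr2 (difference -2.78), the bone morphogenetic protein gene Bmp4 (-2.01), the vasoactive peptide gene Adm (-1.89) and Rspo2, which enhances WNT signalling (-1.80). Klf15 differed by -1.62, the MAP kinase phosphatase gene Dusp1 by -1.51, Runx1t1 by -1.48, the hormone gene Stc1 by -1.48 and Amigo2 by -1.45. Rgs2, Adamts1 and Mab21l2 differed by -1.41, -1.40 and -1.34. In all, 131 of 13308 genes were at least 2-fold apart, 95 higher and 36 lower.

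Gene lists fixed before the data were examined showed which programs moved at 2 h in Snail1-WT cells. Of 18 measured TGF-b early targets, 9 were at least 2-fold higher and none was 2-fold lower. Their median difference of 1.02 lay above the medians of all 10000 random lists matched on expression. Smad7, the inhibitory SMAD gene, was higher by 1.51. The immediate early genes had a median of 0.35, also above all random lists, with 2 of 17 at least 2-fold higher (Egr2 and Ier3, at 1.34) and 1 lower (Dusp1). Components of the TGF-b pathway (median 0.11, percentile 99.0), myofibroblast genes (0.12, percentile 99.7) and extracellular matrix genes (0.10, percentile 99.5) were shifted by far less. Among them the collagen receptor subunit gene Itga11 was higher by 1.26 and Tgfb3 by 0.999, while the smooth muscle actin gene Acta2 differed by 0.07 and Col1a1 by 0.13. Smooth muscle and pericyte markers had a median of 0.23 (percentile 99.6, and 96.8 with the mean of probe sets). The EMT transcription factors had a median of -0.22 (percentile 1.27), with Snai2 at -1.13, Twist1 at -0.76 and Snai1 at 0.94. Hox genes had a median of -0.16 (percentile 0.07), led by Hoxa9 at -0.94 and Hoxa3 at -0.92.

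The response of Snail1-KO cells was also led by Ccn2, which was higher by 3.82, followed by Rasl11b at 3.43, Skil at 3.31, Pmepa1 at 3.06, Egr2 at 2.85, Has2 at 2.58 and Gfpt2 at 2.57. Tnfrsf11b was higher by 2.502 and Hbegf by 2.497. The cytokine gene Il6 was higher by 2.24, the matricellular gene Ccn4 by 2.15 and Rflnb by 2.10. In untreated Snail1-KO cells Il6 measured 4.425 and Rasl11b 4.084, below 4.51, the lowest mean kept, so the sizes and ranks of their increases are uncertain. The largest decreases were those of Osr2 (-2.52), Adm (-2.09), Runx1t1 (-1.92), Bmp4 (-1.77), Adamts1 (-1.75) and the melanocortin receptor gene Mc5r (-1.71). Osr1, a paralog of Osr2, differed by -1.58, Stc1 by -1.47, Rspo2 by -1.44, the neuropeptide Y receptor gene Npy1r by -1.42, Rgs2 by -1.37 and Lbh by -1.32. Stc1 measured 4.383 in treated Snail1-KO cells, below 4.51, so the size of its decrease is uncertain. In all, 174 genes were at least 2-fold apart, 133 higher and 41 lower. For Ccn2, a second and much dimmer probe set gave 1.06 in Snail1-WT and 0.35 in Snail1-KO cells, and the mean over both probe sets gave 1.95 and 2.09. For Rgs2 the mean over its probe sets gave -0.78 and -0.84.

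In Snail1-KO cells 9 of the 18 TGF-b early targets were at least 2-fold higher and 1 was lower (Angptl4, at -1.04), with a median of 1.14 that exceeded all random lists. The immediate early genes had a median of 0.56, with Egr1 at 1.03 and Ier3 at 1.52. The extracellular matrix genes had a median of 0.20 (percentile 100), the TGF-b pathway components 0.14 (percentile 98.8) and the myofibroblast genes 0.14 (percentile 99.3), with Itga11 at 2.01 and Tgfb3 at 1.79. BMP and ID genes had a median of 0.23 (percentile 99.8), matrix proteases and inhibitors 0.14 (percentile 99.2, with Timp3 at 1.08) and mesenchymal stem cell markers 0.22 (percentile 99.8, with Cd200 at 1.48). The p53 targets and cell cycle inhibitors had a median of -0.17 (percentile 0.64). In neither genotype did TGF-b1 move the medians of epithelial, prostaglandin E2, cytokine and NF-kB, interferon-response, adipogenic, osteogenic, chondrogenic, haematopoietic, endothelial, proliferation, hypoxia and glycolysis, sex-linked or housekeeping genes outside the middle 95% of random lists. Over the members in the upper 60% of genes, however, interferon-response (percentile 1.30), haematopoietic (0.26) and Hox genes (0.25) were lower after TGF-b1 in Snail1-KO cells. Single members did differ: the prostaglandin synthase gene Ptgs2 was higher by 0.99 in Snail1-WT and 1.17 in Snail1-KO cells, the angiogenic factor gene Vegfa by 1.53 and 1.23, and the chondrogenic regulator Sox9 by 0.88 and 1.64.

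The 2 responses share no array. Of the genes at least 2-fold higher in either response, 68 were so in both, against 0.949 for independent lists, and 20 were lower in both, against 0.111. No gene was at least 2-fold higher in one genotype and 2-fold lower in the other. Across genes the responses correlated with a Pearson r of 0.633 and a Spearman rho of 0.470, as a description, since genes are not independent replicates. With no filter on low values r was 0.415.

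**Figure D2:**
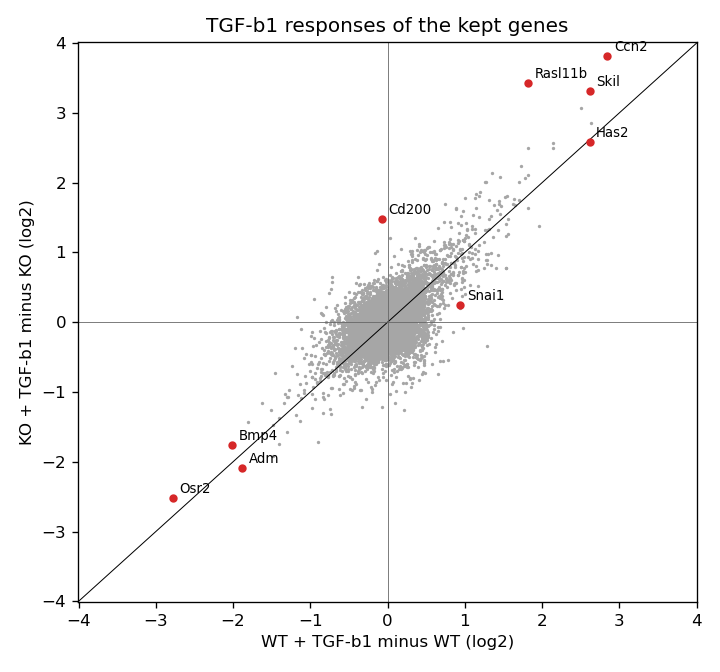
Log2 difference after TGF-b1 in Snail1-WT cells (horizontal axis) and Snail1-KO cells (vertical axis) for 13308 genes, with 1 grey point per gene, named genes in red and the line of equal response. Ccn2, Skil and Has2 lie far from 0 in both genotypes, whereas Snai1 (0.94 and 0.25) and Cd200 (-0.07 and 1.48) lie off the line.

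The largest genotype difference in both pairs was that of asporin (Aspn), a small proteoglycan that binds TGF-b1, which was higher in Snail1-KO cells by 4.23 without and 3.83 with TGF-b1. The palmitoyltransferase gene Zdhhc2 was higher by 3.39 and 3.36, but it measured 2.97 and 3.07 in Snail1-WT cells, under the lower quartiles of all probe sets there (3.62 and 3.65), so the size of its difference and its rank are uncertain. Osteomodulin (Omd) was higher by 2.57 and 2.88, osteoglycin (Ogn) by 1.87 and 1.92, and the chemokine gene Ccl5 by 2.52 and 2.49. The lipocalin gene Apod was higher by 2.21 and 2.19, the water channel gene Aqp1 by 1.95 and 1.94, the carboxylesterase gene Ces1a by 2.13 and 1.89 and Dpysl3 by 2.03 and 1.91. Apol9b, the peptidase gene Mme and Anxa8 completed the 12 largest at 1.74 and 1.66, 1.64 and 1.67, and 1.59 and 1.82. Means over all probe sets of Dpysl3 gave 1.40 and 1.31.

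Lower in Snail1-KO cells were the glutamate receptor gene Gria1 (-2.26 and -2.33), the IGF binding protein gene Igfbp3 (-2.23 and -1.92), the growth factor gene Igf2 (-1.91 and -1.77) and AW551984 (-2.18 and -1.88). The metalloproteinase genes Adam12 (-1.83 and -1.90) and Mmp3 (-1.85 and -1.75) were lower, as were the forkhead factor Foxf1 (-1.77 and -2.42), the small GTPase gene Rhou (-1.76 and -1.74), Cdsn (-1.81 and -1.73) and Cep126 (-1.85 and -1.96). Tissue-nonspecific alkaline phosphatase (Alpl), a marker of bone-forming cells, differed by -1.78 and -1.82, and by -1.17 and -1.23 as the mean of its probe sets. Snai1 was the last of the 12. In Snail1-KO cells Mmp3 and Cep126 lay below 4.51, the lowest mean kept, so the sizes of their differences are uncertain too.

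Mmp3 and Cep126 lie in a stretch of chromosome 9, from Casp1 to Arhgap42 in the gene order of GRCm38.p6, in which 12 of 16 kept genes were at least 1.5-fold lower in Snail1-KO cells in both pairs. The stretch was found after the values were seen. It holds the transcriptional coactivator gene Yap1, at -1.30 and -1.17. Its median was -1.20 without and -1.16 with TGF-b1.

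**Figure D3:**
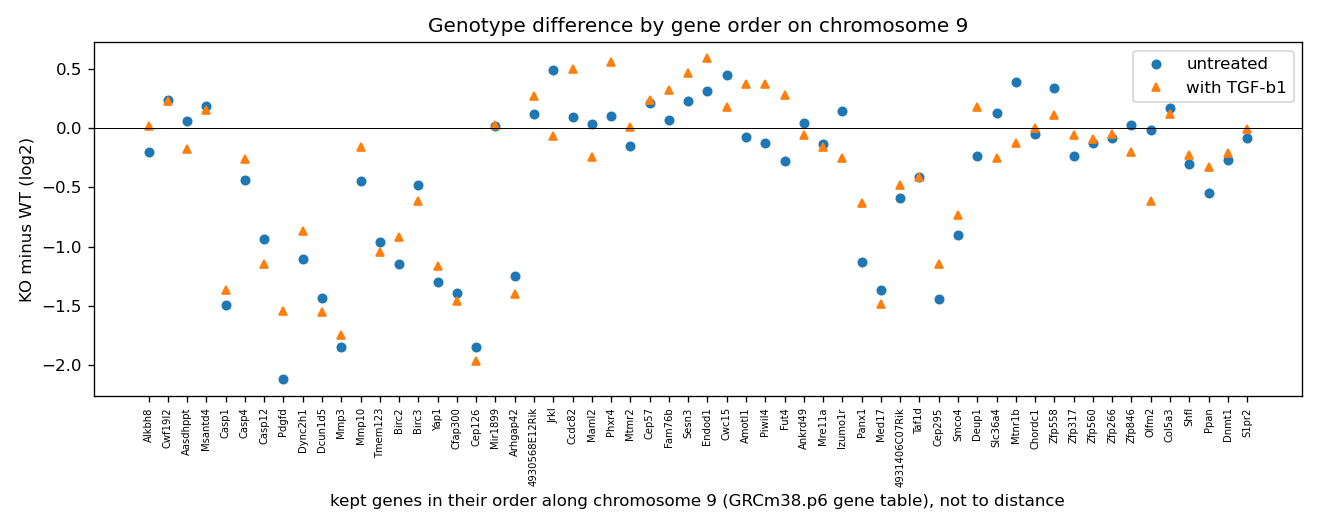
Log2 difference of Snail1-KO minus Snail1-WT cells (vertical axis) without TGF-b1 (circles) and with TGF-b1 (triangles) for kept genes in their order along chromosome 9 (horizontal axis, not to distance). Most genes from Casp1 to Arhgap42 lie well below 0, with medians of -1.20 and -1.16, and the 17 genes between Arhgap42 and Panx1 have medians of 0.09 and 0.27.

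Without TGF-b1, 209 genes were at least 2-fold apart, 110 higher and 99 lower in Snail1-KO cells, and with TGF-b1 226, 142 higher and 84 lower. In both pairs of arrays, which share none, 74 were higher and 63 lower, against 1.17 and 0.625 for independent lists. Whether the cultures of a genotype were separate is not given in the sources used here. A difference between the cell populations unrelated to Snail1 would recur in both pairs too, so the overlap does not replicate an effect of Snail1. A limma fit with additive terms for genotype and treatment, on all 4 arrays with 1 residual degree of freedom, gave 4107 genes for genotype and 2376 for treatment at an adjusted p under 0.05. It borrows its spread from other genes, and its p-values measure only the disagreement between pairs of arrays, pooled over genes of like level. The prior degrees of freedom were infinite, so a gene's own disagreement between the pairs had no weight in its p-value. Without the trend of spread on level these counts were 2345 and 898.

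**Figure D4:**
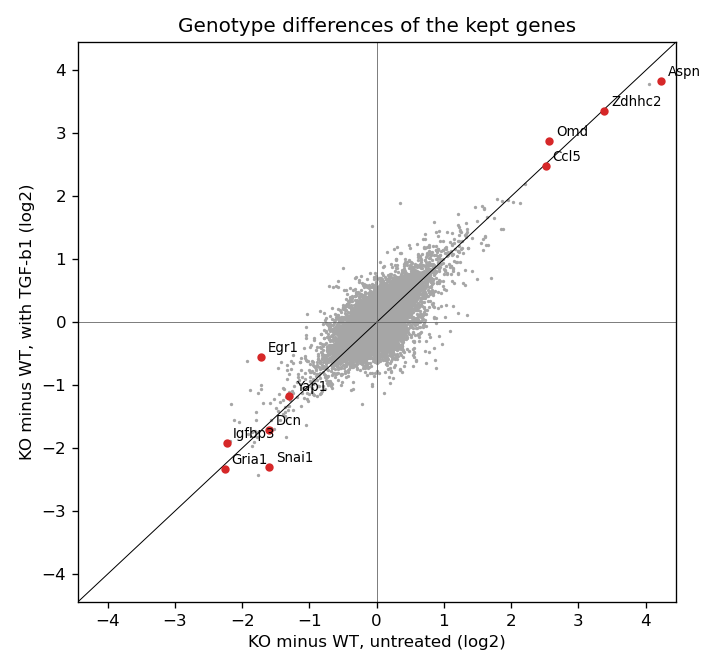
Log2 difference of Snail1-KO minus Snail1-WT cells without TGF-b1 (horizontal axis) and with TGF-b1 (vertical axis) for 13308 genes, with 1 grey point per gene, named genes in red and the line of equal difference. Aspn (4.23 and 3.83) lies at the upper end and Gria1 (-2.26 and -2.33) at the lower end.

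Among the fixed lists, the interferon-response genes stood out in the genotype comparison. Their median was 0.83 without and 0.69 with TGF-b1, above all random lists in both pairs. Of 12 measured members, 4 were at least 2-fold higher in untreated Snail1-KO cells (Ifit1 at 1.88, Oasl2 at 1.29, Cxcl10 at 1.02 and Rsad2 at 1.02) and 3 in treated cells (Ifit1 at 1.49, Gbp3 at 1.18 and Usp18 at 1.07). Gbp3 failed the filter on low values and Rsad2 measured 4.15 in untreated Snail1-WT cells, below 4.51, so the sizes of their differences are uncertain. Immediate early genes were lower in Snail1-KO cells, with medians of -0.33 and -0.28, below all random lists. Egr1 differed by -1.71 and -0.55. With the mean of all probe sets the treated median was -0.13 (percentile 3.17), inside the middle 95%. The TGF-b early targets were lower without TGF-b1 (median -0.33, percentile 0.01, with Ccn2 at -1.06 and Ccn1 at -0.93), and with TGF-b1 their median was -0.11 (percentile 6.61). The dimmer probe set of Ccn2 gave 0.77 without TGF-b1, opposite in sign, and the untreated median of the list was -0.27 (percentile 0.08) with the mean of probe sets.

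BMP and ID genes (median -0.38, below all random lists), matrix proteases and inhibitors (-0.29, percentile 0.04), mesenchymal stem cell markers (-0.24, percentile 0.51) and adipogenic genes (-0.20, percentile 1.61) were also lower in untreated Snail1-KO cells. With TGF-b1 their percentiles were 61.5, 2.58, 40.3 and 58.7. The shift of matrix proteases and inhibitors rested on Mmp3, Mmp10 and Mmp13, which lie between the ends of the chromosome 9 stretch: without these 3 members the untreated median was -0.10 (percentile 14.5). The BMP antagonist gene Grem1 went the other way, at 1.06 and 1.08. Cytokine and NF-kB genes had medians of -0.24 and -0.16 (percentiles 0.19 and 1.45), with Saa3 at -1.37 and -1.34 but Ccl5 higher. Over the members in the upper 60% of genes the untreated median was 0.02, and with cyclic loess the treated percentile was 3.58. Prostaglandin E2 genes had medians of -0.08 without TGF-b1 (percentile 21.2) and -0.29 with it (percentile 0.39), and the difference of their responses did not stand apart (percentile 13.6).

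Epithelial genes did not stand apart, with medians of -0.07 (percentile 19.3) and -0.17 (percentile 8.21). Only 8 of 16 measured members passed the filter on low values, so these medians rest largely on genes near background. Cdh3, at 9.06 in untreated Snail1-WT cells, differed by -0.88 and -0.83. Of the 16 members, 9 were lower in Snail1-KO cells without and 13 with TGF-b1. The Snail1 target Cdh1 measured 4.79 in untreated Snail1-WT cells and differed by 0.19 and -0.06. The EMT transcription factors had medians of -0.05 (percentile 36.2) and 0.17 (percentile 86.5), with Snai2 at 0.39 and 0.64. Myofibroblast genes had medians of -0.13 and -0.04 (percentiles 5.55 and 24.1) over members that went both ways: Tnc differed by -1.70 and -1.28, Cnn1 by -0.90 and -0.76, and Postn by 1.12 and 1.07. Over the members in the upper 60% of genes the untreated median was -0.21 (percentile 0.85). Extracellular matrix genes had medians of 0.03 and 0.10 (percentiles 67.0 and 94.5), with Col11a1 at 0.98 and 1.15 and decorin (Dcn) at -1.59 and -1.71. Osteogenic genes had medians of 0.19 and -0.11 (percentiles 97.2 and 26.1), with Phex at 1.20 and 1.09 beside Omd and Alpl. Phex failed the filter, at 3.79 and 3.53 in Snail1-WT cells, so these sizes are uncertain. TGF-b pathway components had medians of -0.10 and -0.10 (percentiles 11.6 and 6.61).

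Markers of other cell types spanned a range of levels. In untreated Snail1-WT cells the pan-leukocyte gene Ptprc measured 3.15 and the endothelial gene Pecam1 4.46, but the macrophage marker Cd68 measured 6.18 and the smooth muscle genes Lmod1 and Smtn 6.25 and 8.20. Cd14 measured 6.175, but other macrophage genes were low, with Adgre1 at 3.41, Itgam at 3.77 and Csf1r at 4.84. Of 13 haematopoietic markers, 5 passed the filter on low values, so Cd68 alone is no sign of macrophages. Haematopoietic markers had a median genotype difference of 0.21 without TGF-b1 (percentile 98.9) and -0.13 with it (percentile 21.3), and the untreated percentile was 90.9 over the members in the upper 60% of genes. Endothelial (percentiles 33.4 and 18.7), smooth muscle and pericyte (83.7 and 46.2), chondrogenic (40.8 and 35.8), proliferation (31.0 and 47.8), p53 target and cell cycle inhibitor (13.8 and 5.64), hypoxia and glycolysis (10.99 and 44.3), Hox (11.4 and 89.3), sex-linked (3.68 and 26.6) and housekeeping genes (63.2 and 54.3) lay inside the middle 95% of random lists in both genotype pairs. The proliferation gene Mki67 differed by 0.02 and -0.07.

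Whether TGF-b1 acted differently without Snail1 was addressed by subtracting the response of Snail1-WT cells from that of Snail1-KO cells. The difference was 1.61 for Rasl11b, a small GTPase gene, and 1.55 for Cd200, an immune-regulatory surface protein gene whose response was -0.07 in Snail1-WT and 1.48 in Snail1-KO cells. The difference was 1.36 for Zfp458, 1.30 for Akr1c18, 1.28 for Gdpd3, 1.24 for H4c17, 1.21 for Id2, an inhibitor of basic helix-loop-helix factors, and 1.19 for the phosphodiesterase gene Pde7a. In the other direction it was -1.62 for Spin2d, -1.25 for C1s1, -1.24 for Trp63, -1.24 for AI661453, -1.23 for Sybu, -1.23 for Cyp4a12b, -1.20 for Ceacam2 and -1.19 for Spag6. Of these 16 genes, 9 lay below 4.51 on at least 1 array (Rasl11b, Cd200, Akr1c18, Spin2d, Trp63, AI661453, Sybu, Cyp4a12b and Spag6), so the sizes of their differences are uncertain. In all, 45 genes were at least 2-fold apart, 14 higher and 31 lower in Snail1-KO cells. Of these 30 were in the lowest quintile of genes by level, and over the upper 40% of genes 4 remained past the threshold, 3 higher and 1 lower. More genes were lower than higher with no filter (89 higher and 108 lower), at 1.5-fold (214 and 262), with median centring (11 and 40), with cyclic loess (16 and 27) and with the mean of probe sets (14 and 29). As the mean of all probe sets the difference was -0.35 for C1s1, -0.71 for Spin2d, -0.74 for Spag6 and 0.92 for Pde7a.

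The TGF-b early targets responded more in Snail1-KO cells by a median of 0.18 (percentile 99.8), with Ccn2 at 0.98, Skil at 0.70 and Ccn1 at 0.64. The dimmer probe set of Ccn2 gave -0.71, opposite in sign, and the median of the list was 0.14 (percentile 98.5) with the mean of probe sets. The immediate early genes had a median difference of 0.19 (percentile 99.8), with Egr1 at 1.17, and BMP and ID genes 0.23 (percentile 99.3). EMT transcription factors (0.20, percentile 99.2), extracellular matrix genes (0.10, percentile 99.0), adipogenic genes (0.20, percentile 98.2), Hox genes (0.12, percentile 98.2) and matrix proteases and inhibitors (0.10, percentile 97.6) also lay above the middle 95%. Extracellular matrix genes with the mean of probe sets (percentile 97.48), adipogenic genes with cyclic loess (97.0) and Hox genes in the upper 60% (90.7) did not. Mesenchymal stem cell markers with the mean of probe sets (98.3, against 95.8) and endothelial markers in the upper 60% (98.2, against 38.8) did. The untreated arrays enter both this difference and the untreated genotype difference. A list lower in untreated Snail1-KO cells is thus no separate evidence of a larger response.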

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

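All tests in this part were chosen after the results they bear on were seen.

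Several genes had measured responses to TGF-b1 of opposite sign in the genotypes, which was not tested. The difference of the responses was 1.55 for Cd200, 1.36 for Zfp458, 1.30 for Akr1c18, 1.28 for Gdpd3, 1.24 for H4c17 and 1.21 for Id2. It was -1.62 for Spin2d, -1.39 for Olfr370 (an olfactory receptor gene outside the naming rule, added after its values were seen because both responses passed 1.5-fold), -1.25 for C1s1, -1.24 for Trp63, -1.24 for AI661453, -1.23 for Sybu, -1.23 for Cyp4a12b, -1.20 for Ceacam2 and -1.19 for Spag6. For 3 of these 15 genes the smaller response lay within its noise SD, so that its sign is not known: Cd200 (-0.07 in Snail1-WT cells, noise SD 0.22), C1s1 (0.10 in Snail1-WT cells, 0.21) and H4c17 (0.07 in Snail1-KO cells, 0.21). Others barely passed it, such as Cyp4a12b (0.227 in Snail1-WT cells, noise SD 0.212) and Sybu (0.304 in Snail1-WT cells, 0.222). The genes were picked for large differences, and noise can exceed 1 noise SD, so passing it does not establish the sign of the others. Of the 15 genes, 9 lay below 4.51 on at least 1 array, Olfr370 among them, so the sizes of their differences are uncertain. Noise of weakly expressed probe sets is a candidate explanation for some of the genes past 2-fold in this difference: 30 of the 45 lay in the lowest quintile by level and 0 in the highest, whose SD of the difference was 0.14 against 0.34. Normal noise with the SD of each quintile would put 12.2 genes past 2-fold, 9.56 of them in the lowest quintile, and with an SD from the median absolute deviation, which gives less weight to outlying genes, 6.14 and 3.94. Whether the noise has wider tails was not tested, so the share of the 45 that it accounts for is not known. Id2, at 6.61 in untreated Snail1-WT cells, and Pde7a, at 6.86, are above that range, and their differences stay open.

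Among 6386 probe sets not named here that passed the filter on low values, 41 were at least 2-fold apart by genotype in both pairs of arrays, 24 higher and 17 lower in Snail1-KO cells, against 2.03 and 1.96 for independent lists. They were in none of the comparisons above. For them too, a difference between the cell populations unrelated to Snail1 would recur in both pairs.

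Genes induced by TGF-b1 were higher by more in Snail1-KO cells. Over the 50 genes with the largest sum of both increases the median was 1.49 in Snail1-WT and 1.76 in Snail1-KO cells, and 41 of 50 responded more in the latter. A wider scale of values on the Snail1-KO arrays would enlarge decreases too, but the 50 most decreased genes had a median ratio of responses of 0.931, against 1.17 for the increased ones. The 50 increased genes differed between genotypes by a median of -0.33 before and -0.027 after TGF-b1. Per gene, the difference of the responses equals the treated minus the untreated genotype difference, so these medians largely restate the larger increase. They cannot decide whether a lower starting level in untreated Snail1-KO cells, or a deviation of that 1 array, accounts for it. A less stimulated state of the untreated Snail1-KO culture at harvest stays open. Immediate early genes outside those 50 were lower there (15 genes, median -0.28, percentile 0.06, against 7.47 with TGF-b1), but the whole list of 17 was lower with TGF-b1 too (median -0.28, percentile 0), so the result depends on 2 members. With 1 culture per group an effect of Snail1 stays open as well.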

How the results depend on the processing

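The chromosome 9 alternatives were chosen after seeing the data. At 1.5-fold the counts were 581 for the response of Snail1-WT cells, 684 for that of Snail1-KO cells, 951 and 1083 for the genotype difference without and with TGF-b1, 566 for both pairs and 476 for the difference of the responses, as a lower threshold must give. With no filter on low values the difference of the responses counted 197 genes and over the upper 40% of genes 4, and the correlation of the responses without the filter was 0.415. The limma genotype and treatment terms counted 2345 and 898 genes without a trend. The causes of these shifts were not tested. Every other count stayed within 1.5 times its main value under no filter, the filter at 40%, median centring, cyclic loess, the mean of probe sets, the robust fit and, for genotype, without 22 genes of chromosome 9, where 127 remained in both pairs. The median of cytokine and NF-kB genes in untreated cells turned from -0.24 to 0.0167 over members in the upper 60% of genes, with fewer members. Of the other list medians, 362 kept their call or their lack of a call under an alternative, 8 lost a call and 6 gained one. Among the calls lost was that of matrix proteases and inhibitors in untreated cells, at -0.10 without members from the chromosome 9 stretch. Because the 362 include medians that stood apart under neither setting, they do not give the share of calls that held. For named genes, 212 values stayed within the noise SD and 12 moved, all 12 with the mean of probe sets. Replicates could not be paired because each group has 1 array. The genotypes were compared within each treatment by subtraction, whereas the additive fit gave 1 genotype term over both treatments. Signal near background limits the genes below 5.13, the top of the lowest quintile.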

Other observations

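The hypothesis on YAP targets was written before its result was seen, and the tests and the genes named on chromosome 9 were chosen after their values were seen.

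Small leucine-rich proteoglycans, matrix proteins that bind collagen and growth factors, did not stand apart by genotype as a list, which was drawn up after seeing some of its values, but single members differed. Aspn, Omd and Ogn were at least 2-fold higher in Snail1-KO cells in both pairs. Whether these are independent changes or a shared change of neighbouring genes was not examined, so they should not be counted as separate effects. The medians over windows of 9 neighbouring genes used below can miss a smaller cluster and do not settle it. Dcn (-1.59 and -1.71) and fibromodulin (Fmod, -2.16 and -1.30) were lower. Biglycan (Bgn), at 12.85 in untreated Snail1-WT cells, differed by 0.01 and -0.01. The median of 15 measured members was 0.12 without and 0.11 with TGF-b1 (percentiles 92.4 and 92.0). Ecm2 was also higher in Snail1-KO cells (1.16 and 1.29), but it failed the filter on low values, at 3.86 and 3.79 in Snail1-WT cells, so the size of its difference is uncertain. The Y-linked genes Eif2s3y, Kdm5d and Uty measured 7.08, 6.37 and 6.30 in untreated Snail1-WT and 6.84, 5.77 and 6.002 in untreated Snail1-KO cells, and Xist 3.22 and 3.29.

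A stretch of neighbouring chromosome 9 genes was lower in Snail1-KO cells, from Casp1 to Arhgap42 in the gene order of GRCm38.p6. Of 16 kept genes, 12 were at least 1.5-fold lower in both pairs, with medians of -1.20 and -1.16. They include the transcriptional coactivator Yap1 (-1.30 and -1.17), Dcun1d5 (-1.44 and -1.56), the growth factor gene Pdgfd (-2.12 and -1.55) and Mmp3, whereas Casp4 differed by -0.44 and -0.26. In 0 of 1000 shuffled gene orders did any window of 9 genes reach the real minimum of -1.24, which argues against unrelated genes that lie side by side by chance. Probe sequence shared within gene families was tested on the 9 genes outside the caspase, metalloproteinase and Birc families, whose median was -1.33, below every shuffled window. The stretch was chosen for its low windows, so a low median of its genes was close to fixed in advance. The value shows only that the low values were not confined to these families. A difference in copy number of the region may be involved and cannot be told apart from regulation of the region: 75% of its kept genes were lower by 1.5-fold, the ends were set from these genes, and DNA was not measured.

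Further along, 17 kept genes had medians of 0.09 and 0.27, and then Panx1 (-1.13 and -0.64), Med17 (-1.36 and -1.49), Cep295 (-1.45 and -1.15) and Smco4 (-0.90 and -0.74) were lower. This group was picked by eye. Its lowest window had a median of -0.53, and 18 of 1000 shuffled orders held a window as low anywhere (median of their lowest windows -0.39). In all, 4 of the 6 kept genes of this group were at least 1.5-fold lower in both pairs. Taf1d was not, at -0.41 and -0.41 on the brightest probe set, which represents the gene. All 11 further probe sets of 2 of its genes, 10 of Taf1d (2 with identical values) and 1 of Cep295, were at least 1.5-fold lower in both pairs. They carry symbols of genes already in the group and add no independent genes. Which RNAs of these genes each probe set measures was not examined. The 20 kept genes around Snai1, on chromosome 2, had a median absolute genotype difference of 0.21 (percentile 78.9 among runs of 20 genes).

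Lower Yap1 led to the hypothesis of reduced YAP target expression in Snail1-KO cells, tested on a list without members whose values had been seen. In untreated cells 14 of 17 measured targets were lower, with a median of -0.37 at percentile 0 of matched random lists, for example Crim1 at -0.56 and Ajuba at -0.51. In treated cells the median was -0.14 at percentile 2.53, and the bound set beforehand, under 2.5 in each pair, was missed there. For the mean of both pairs, which was not part of that prediction, the median was -0.34 at percentile 0, with 14 of 17 lower. Reduced YAP target expression may thus hold, most clearly in untreated cells, and stays open because the treated pair missed the bound and each group has 1 array. TGF-b early targets were lower in untreated Snail1-KO cells too (15 of 18 members), but that list holds Ccn2 and Ccn1, which are also YAP targets. Immediate early genes (median -0.33) and BMP and ID genes (median -0.38) were lower there as well, so the shift was not confined to YAP targets.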
